A study of Arabidopsis thaliana with 8 samples.

How the data were processed

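The series profiled N6-methyladenosine (m6A), a methyl mark on adenosines of messenger RNA, by miCLIP-seq in leaves of Arabidopsis thaliana ecotype Col-0. In this assay an antibody against m6A is crosslinked with ultraviolet light to poly(A)+ RNA and the bound RNA is sequenced. Per the labels' protocols, plants grew in soil at 22 °C with 16 h of light and 8 h of dark, and leaves 5 to 9 were taken from plants 4 weeks old, 4 h after first light. Each replicate used 7 µg of poly(A)+ RNA, and the libraries were strand-specific. The labels describe 8 libraries in 4 groups of 2: an m6A-bound fraction and an unbound supernatant for each of 2 genotypes. The genotypes are wild type and ABI3:MTA, written mta below, in which the MTA methyltransferase is driven by the embryo-active ABI3 promoter. The 4 bound libraries have peak lists, which are analysed here. The supernatant libraries have no list of their own and were not analysed here. Nothing in the labels says whether replicates came from separate plants, so the spread between them may be technical.

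Per the submitters' processing notes, STAR 2.4.0, MACS2 and the TAIR10 genome were used; the MACS2 version, the control and the threshold are not given in the sources used here. Each deposited list gives a chromosome, start, end, name, score and strand for every peak. The peak names show that the authors called peaks on each library alone and on each strand apart. The score is the authors' own whole-number value for the peak, and its scale is stated by no header. It was used to rank peaks within a list, both strands together, and, at 1 fixed cutoff, to filter every list. The lowest score was 13 in both wild-type lists and in mta replicate 1, and 20 in mta replicate 2, whose peaks also carry a differently built name. The lists hold no summits, fold enrichments, p-values or read counts. The read depth of each library is therefore unknown, and the number of peaks is the only measure of yield.

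The plan fixed before the data were examined named summits and q-values. Because the lists lack them, the midpoint of a peak took the place of its summit, and the score took the place of the q-value. The stricter threshold was a score of at least 50, a choice that rests on an unproven reading of the score as a scaled q-value. Ranking by fold enrichment was not run, and the planned comparison of summit with midpoint had nothing to compare. Ties between named genes went to the lower gene identifier.

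Positions were placed on the RefSeq copy of the TAIR10 assembly (TAIR10.1). Every peak end lay within its chromosome in that copy, and 97.5% of the 19583 peaks had their midpoint in an exon on the same strand, against 0.470% antisense to one. Mitochondrial peaks were counted but not placed on genes. A midpoint in exons of more than 1 gene on the same strand was left out as ambiguous. Each gene was represented by the coding transcript with the longest coding sequence (CDS). Peaks whose midpoint fell outside that transcript were left out of the location and motif results; these were 249 and 169 peaks in wild-type replicates 1 and 2, and 30 and 31 in mta.

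Peaks of different lists were called shared when they overlapped by at least 1 bp on the same strand. Peaks of both replicates of a genotype were merged into regions, and a region counted as reproducible when both lists contributed. Overlaps were set beside 1000 random placements of the compared list's peaks on exons of their own genes. Location shares were set beside 1000 random placements on the gene's own transcript, and motif shares beside 1000 placements in the same gene and feature class. RRACH, the textbook consensus of m6A (R is A or G, H is A, C or U), was searched on the gene's strand of the genome within 50 nt of each midpoint. Genotypes were compared with exact two-sided permutation tests, which with 2 libraries against 2 cannot give a p below 0.333. Across regions and genes, two-sided Fisher's exact tests were used, with Benjamini-Hochberg adjustment over gene lists that had at least 5 genes in both wild-type lists. Regions and genes are not independent replicates of the plants, so such p-values describe these lists. Intervals are Clopper-Pearson 95% intervals and cover counting error only.

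The gene lists (273 genes in 16 lists) were written before the data were examined. Genes named in the text follow a rule fixed at the same time. It takes the 15 genes with a peak in both wild-type lists and none in mta that have the highest mean score percentile in wild type. It adds the 10 highest-ranked genes with a peak in all 4 lists and the 5 highest-ranked with a peak in both mta lists alone. It also takes every m6A writer, reader and eraser with a peak in any list, and of each other list up to 4 members with a peak in both wild-type lists. Other genes named were chosen after their values were seen, and the text says so. The plan listed 41 alternatives, covering the threshold, the overlap rule, list length, gene model, motif and window, the replicate block and each replicate left out; 3 more were added after seeing the data.

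The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures used matplotlib 3.10.9 and the search for similar 3' UTRs BLAST 2.17.0. The functions were tested on simulated data. With regions removed at known rates by rank, the simulated 81.1% without an mta peak over 5513 regions was recovered as 81.1%. For 6231 peaks moved so that 80.7% should carry RRACH, 81.1% was recovered. In simulated gene lists drawn from 5194 genes, 1 planted list was called and 0 of 40 random lists were. The planted list was larger than any list tested here and had a lower share without an mta peak. Its call therefore does not show power for the smaller real lists.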

Results

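Peaks of m6A-bound RNA were compared between wild-type and mta leaves, with 2 libraries of each genotype. The lists held 8973 and 6584 peaks in wild-type replicates 1 and 2, and 1934 and 2092 in mta replicates 1 and 2. The series' design names the contrast of these genotypes, and the comparison asks which transcripts carry m6A-bound regions in one genotype and not in the other. A gene without a peak had no region called there by the authors; its RNA level was not measured in these lists. The number of peaks is all that is known of the depth of a library.

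Far fewer regions were called in mta. Wild-type libraries had 7779 ± 1689 peaks (SD, n = 2) and mta libraries 2013 ± 112 (SD, n = 2), 3.86 times as many in wild type, and the genotypes did not overlap (exact permutation p = 0.333, the smallest this design allows). Protein-coding genes with a peak numbered 6505 ± 1314 in wild type and 1596 ± 75.0 in mta (SD, n = 2 each). Peaks were also narrower in mta, with median widths of 56 and 54 bp against 88 and 83 bp. The bases covered were 6.38 times as many in wild type. With scores of at least 50 the libraries overlapped, at 4517 and 647 peaks in wild type and 322 and 1171 in mta (exact permutation p = 0.667).

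Replicates of a genotype shared more peaks than libraries of different genotypes. Of the peaks in wild-type replicate 2, 87.4% met a peak of wild-type replicate 1, where random placement within the same genes gave 15.3%, and 63.2% of replicate 1 met replicate 2. In mta, 50.5% of replicate 1 met replicate 2 and 46.7% of replicate 2 met replicate 1, against 11.2% and 10.1% by placement. Of the peaks of wild-type replicate 1, 8.94% and 7.43% met mta replicates 1 and 2, against 2.60% and 2.23% by placement; the short mta lists limit these shares. Of the peaks of mta replicates 1 and 2, 42.4% and 32.4% met wild-type replicate 1, against 11.5% and 8.99% by placement. With scores of at least 50, 59.0% of the 322 peaks of mta replicate 1 met replicate 2, and 16.3% of the 1171 peaks of replicate 2 met replicate 1, a share limited by the shorter list.

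Most regions found in both wild-type libraries had no counterpart in mta. There were 5513 such regions, and 4686 of them (85.0%, interval 84.0 to 85.9%) met no peak of either mta list; 357 met both mta lists and 470 met 1. For the other splits of the 4 libraries, 87 of the 796 regions shared by wild-type replicate 1 and mta replicate 1 were absent from the remaining libraries, and 36 of the 662 shared by wild-type replicate 1 and mta replicate 2. The length of the mta lists caps these counts. The remaining libraries of these splits also include a wild-type list, which itself meets many peaks of the other wild-type list. These counts are therefore no control for the effect of genotype.

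At the gene level, 5194 protein-coding genes had a peak midpoint in both wild-type lists and 3849 of these (74.1%, interval 72.9 to 75.3%) had none in mta. The highest-ranked included STT3A (AT5G19690), a subunit of the oligosaccharyltransferase that glycosylates proteins, with a peak in the 3' UTR on chromosome 5 from 6658226 to 6658411 that scored 161 and 58 in wild-type replicates 1 and 2. RBP45A (AT5G54900), an RNA-binding protein, had its 3' UTR peak on chromosome 5 from 22298172 to 22298328, with scores of 152 and 58. HMG (AT3G28730), annotated as a high mobility group protein, had one on chromosome 3 from 10788441 to 10788624 with the same pair of scores. PEX11D (AT2G45740), a peroxisome membrane protein, and SAD1 (AT5G48870), an Sm-like protein of small nuclear ribonucleoproteins, scored 132 and 134 in replicate 1 and 58 each in replicate 2. UBC21 (AT5G25760), a ubiquitin-conjugating enzyme often used as a reference transcript, scored 125 and 58. The other 9 genes of this group were AT2G24420, AT2G32160, AT3G58130, AT5G13030, AT5G04750, AT5G36230, AT2G01090, AT2G42910 and AT3G15780. All 15 had their best peak in the 3' UTR. All 15 also lay on the plus strand and scored 58 in wild-type replicate 2. Peaks were called on each strand apart but ranked together, and whether scores compare between strands was not tested. The ranking may thus favour 1 strand. The count of genes without an mta peak varied with list length and threshold, and their share less so: the count was 839 of 1191 (70.4%) with every list shortened to the 1934 peaks of the shortest, 471 of 588 (80.1%) with scores of at least 50, and 5818 of 7434 (78.3%) without wild-type replicate 2. Over the leave-one-out alternatives the share ran from 74.3 to 82.1%.

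A smaller set of genes had peaks in all 4 libraries, 532 in number. UBC4 (AT5G41340), another ubiquitin-conjugating enzyme, had a 3' UTR peak on chromosome 5 from 16538107 to 16538257, with scores of 144 and 50 in wild type and 55 and 83 in mta. SDH8 (AT2G46390), a succinate dehydrogenase subunit of mitochondrial complex II, scored 95 and 50 in wild type and 79 and 96 in mta. AT2G34160, an Alba-type DNA- and RNA-binding protein, scored 95 and 58, and 76 and 91. The others were LCV2, AT1G01230, an ORMDL family protein, AT1G55090, AT1G78140, AT3G45050, AT2G36410 and AT4G09580. Scores are given to identify the peaks and were not compared between lists.

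How often a wild-type region was met by an mta peak differed little across its rank in wild type. The 5513 regions were split into 4 rank groups of equal size by mean wild-type score percentile, and from the lowest to the highest group 14.2%, 12.3%, 14.9% and 18.6% met an mta peak. The top and bottom groups differed (two-sided Fisher's exact p = 0.00202 across regions), yet only 256 of the 1378 regions in the top group met one and 81.4% did not. In a comparison chosen after seeing the data, all peaks of a wild-type list were set against the other wild-type list shortened to its 3047 highest-scoring peaks, as many as the merged mta regions. Of all peaks of wild-type replicates 1 and 2, 11.5% (interval 10.9 to 12.2%) and 13.9% (13.1 to 14.7%) met an mta peak, and 33.0% (32.0 to 33.9%) and 44.2% (43.0 to 45.5%) met the shortened list. The compared lists were matched in number and not in peak width.

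**Figure D1:**
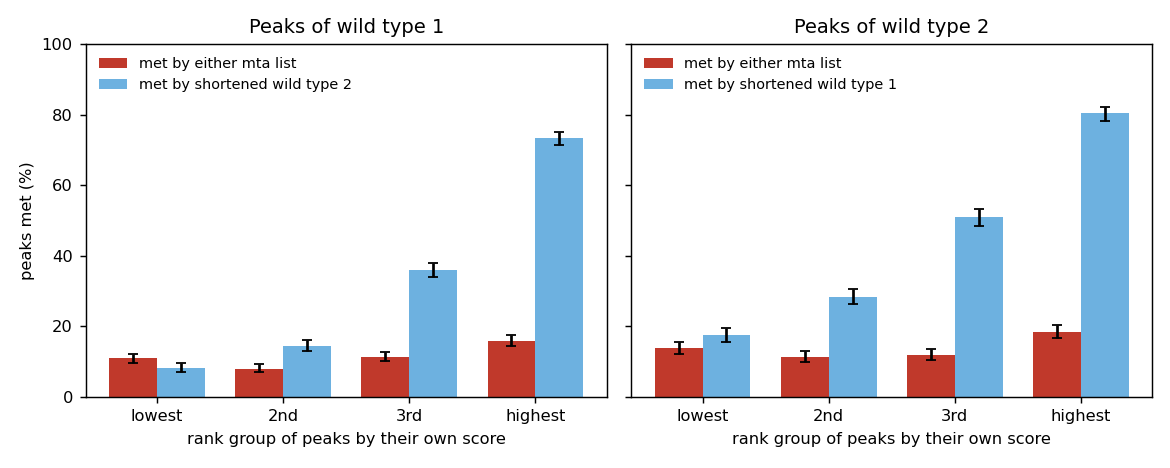
Share of the peaks of wild-type replicate 1 (left) and 2 (right) met by a peak of either mta list or by the 3047 highest-scoring peaks of the other wild-type list (vertical axis, percent), in 4 rank groups of the peaks by their own score (horizontal axis). Bars are shares and error bars Clopper-Pearson 95% intervals. From the lowest to the highest group the mta share goes from 10.9% to 15.8% in replicate 1 and from 13.9% to 18.4% in replicate 2, and the share of the shortened list from 8.24% to 73.3% and from 17.4% to 80.3%.

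Some regions were found in mta alone. Of 973 regions in both mta lists, 484 (49.7%, interval 46.6 to 52.9%) met no wild-type peak, and 184 protein-coding genes had peaks in both mta lists and in neither wild-type list. The highest-ranked were AT1G10390, annotated as a nucleoporin autopeptidase, CDT1 (AT1G52827), a cadmium tolerance protein, AGP10 (AT4G09030), an arabinogalactan protein of the cell surface, AT2G09970 and AT3G53650, a histone. The AT1G10390 peak lay in the CDS on chromosome 1 from 3409780 to 3409842 and scored 85 and 140 in mta replicates 1 and 2. The AGP10 peak lay in the CDS on chromosome 4 from 5792589 to 5792656 and scored 82 and 123. All 5 of these genes had their best peak in the CDS.

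Where peaks lay within transcripts differed between genotypes. In wild type, 91.1% ± 0.496 of placed peaks were in 3' UTRs and 8.51% ± 0.407 in coding sequence; in mta the shares were 49.1% ± 6.38 and 48.1% ± 5.70 (SD, n = 2 each; exact permutation p = 0.333 for both). The 3' UTR peaks numbered 6707 ± 1486 in wild type and 859.5 ± 84.1 in mta, 7.80 times as many in wild type. Peaks in coding sequence were not fewer in mta, at 845 ± 127 against 622.5 ± 105 in wild type (SD, n = 2 each). Random placement on the same transcripts gave 19.7% and 20.4% in 3' UTRs for the wild-type libraries, and 24.6% and 22.1% for mta. Within 100 nt of the stop codon lay 38.0% ± 0.629 of the wild-type and 30.7% ± 2.00 of the mta peaks (SD, n = 2 each). Among 3' UTR peaks, the median distance past the stop codon was alike, at 121 and 120 nt in wild type and 117 and 116 nt in mta. Among peaks of at least 75 bp, an alternative chosen after seeing the data, the 3' UTR share fell by 26.5 percentage points from wild type to mta, against 42.0 for all peaks.

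**Figure D2:**
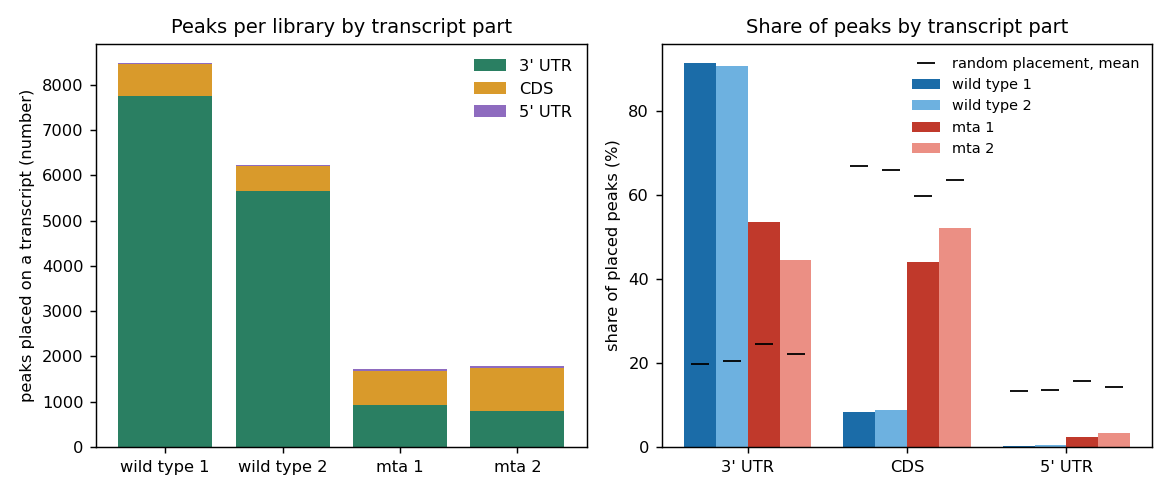
Left, the number of peaks placed on a representative transcript in each library, stacked by 3' UTR, CDS and 5' UTR; right, the same as a percent of placed peaks, 1 bar per library, with a dash for the mean of random placements. The 3' UTR holds 91.5% and 90.8% of the placed wild-type peaks and 53.6% and 44.6% of the mta peaks.

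**Figure D3:**
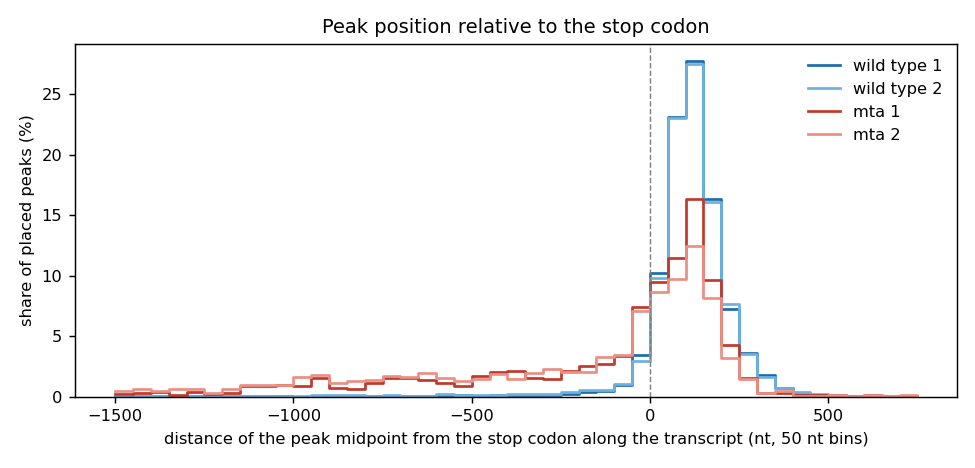
Share of placed peaks (vertical axis, percent) by distance of the midpoint from the stop codon along the transcript (horizontal axis, nt, bins of 50 nt), 1 line per library. Each library has its highest bin from 100 to 150 nt past the stop codon, holding 27.8% and 27.6% of wild-type and 16.4% and 12.5% of mta peaks, and the mta lines lie above the wild-type lines upstream of the stop codon.

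Regions also differed by whether the other genotype shared them. Wild-type regions with and without an mta peak both lay mainly in 3' UTRs, at 98.3% of 784 and 96.0% of 4455 (Fisher's exact p = 0.00061). The mta regions that met a wild-type peak lay in 3' UTRs in 87.6% of 445 cases. Those that met none did so in 21.7% of 387, with 74.4% in coding sequence (Fisher's exact p = 2.06e-88 across regions). Wild-type peaks lay mostly in 3' UTRs (mean 91.1%), so an mta region that met one was likely to lie there too. That p-value was thus largely set by the way the regions were split.

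The RRACH consensus was found slightly more often than placement gave. Of wild-type peaks, 77.3% ± 0.0803 had it within 50 nt, and 72.9% ± 0.914 of mta peaks did (SD, n = 2 each; exact permutation p = 0.333). The excess over placement in the same gene and feature was 5.14 percentage points in wild type and 2.99 in mta. Regions with and without an mta peak carried it in 76.0% and 78.3% of cases (two-sided Fisher's exact p = 0.161). URUAY, a plant motif reported near m6A (R is A or G, Y is C or U), was found near 56.9% ± 0.253 of wild-type and 42.7% ± 2.71 of mta peaks (SD, n = 2 each), 7.97 and 3.45 percentage points above placement. The RRACH excess depended on the window: within 25 nt it was 9.95 points in wild type and 6.24 in mta, and within 100 nt 0.0173 and -0.915. With DRACH, a broader consensus, it was 3.82 and 1.66 points.

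No gene list passed the test for a share without an mta peak that differs from other genes, but the lists were too small to pass for a higher share. If all genes of a list lacked an mta peak, the unadjusted Fisher's exact p would be 0.0771 for the largest list tested, of 11 genes, and 0.349 for the smallest, of 6, so the test could pass only for a lower share. Among the 4 lists with at least 5 genes in both wild-type libraries, the lowest adjusted p was 0.806 (Fisher's exact test, Benjamini-Hochberg), and 0 lists passed at an unadjusted p of 0.05. Without wild-type replicate 1, 2 of 6 defence genes (33.3%) lacked an mta peak (unadjusted Fisher's exact p = 0.0413, adjusted 0.207). Among the 4 lists tested, trichome genes had the highest share, and 0 of their 25 members had a peak in either mta list. Of the 7 trichome genes with a peak in both wild-type lists, 7 lacked an mta peak, against 74.1% of all 5194 (unadjusted Fisher's exact p = 0.202, adjusted 0.806). They included TTG1, a WD40 protein needed for trichome initiation, with a 3' UTR peak on chromosome 5 from 8370752 to 8370955, KAK, a ubiquitin ligase that limits trichome branching, and the actin-nucleation genes DIS2 and ARP2.

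Clock and light genes had peaks in 11 of 28 members in both wild-type lists, and 9 of these had none in mta (adjusted Fisher's exact p = 0.986). PHYB, the red-light photoreceptor, had a 3' UTR peak on chromosome 2 from 8144276 to 8144405 in wild type alone, as did the clock transcription factor RVE6. RVE8 and RVE4, related clock factors, had peaks in all 4 libraries. Of the mRNA decay genes 6 had peaks in both wild-type lists and 5 of these had none in mta, UPF3, VCS and XRN2 among them (adjusted Fisher's exact p = 1); AGO1, the slicer of small RNA silencing, had one in mta replicate 1. Of the reference genes 7 had peaks in both wild-type lists and 6 of these had none in mta (adjusted Fisher's exact p = 0.986), among them UBC21, PP2AA3 and TIP41, whereas ACT8 had a peak in mta replicate 1.

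Genes of the m6A machinery with a wild-type peak had none in mta, as did most genes (74.1% of those with a peak in both wild-type lists), and these lists were too small for the planned test. Without wild-type replicate 2 the readers had enough genes for the test: 6 of 6 lacked an mta peak (Fisher's exact p = 0.351, adjusted 0.728). That is the lowest p that 6 genes can give for a higher share, so the test could not pass in that direction. Of the writers, FIP37 and VIR had a peak in wild-type replicate 1 and HAKAI in both replicates. Of the YTH readers, ECT1, ECT3, ECT5, ECT6 and ECT8 had one in wild-type replicate 1 and ECT10 in both. Of the ALKBH demethylases, ALKBH10B had a peak in both wild-type lists and ALKBH9C in replicate 2. MTA had no peak in any list, so the lists give no check of the genotype at that gene.

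Other lists had few genes in both wild-type libraries. Cold, drought and salt response had 4 of 36, of which ABF3 and ABF4, transcription factors of abscisic acid signalling, lacked an mta peak while ERD1 and NHX1 had one in both mta lists. Defence had 4 of 18, with RBOHD and CERK1 lacking an mta peak and BAK1 and SYP121 having one in mta replicate 1. Cytosolic ribosome had 4 of 21: RPL23AB, RPS18A and RPL4A lacked an mta peak and RPS5B had one in mta replicate 1. Of the 55 nuclear photosynthesis genes, 0 had a peak in either wild-type list. Markers of guard cells, phloem, epidermis, xylem and seed had 0 members in both wild-type lists.

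**Figure D4:**
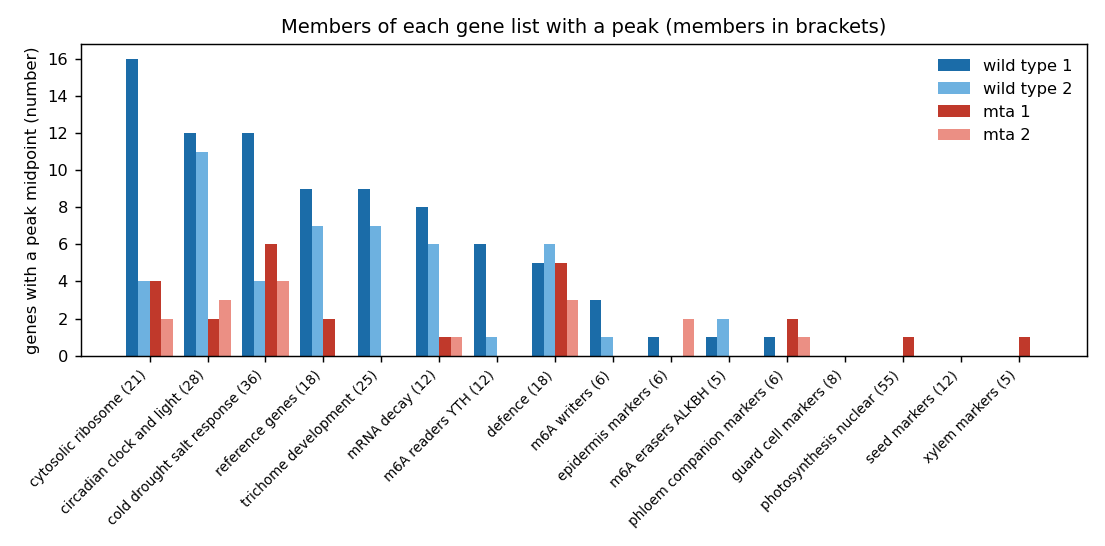
Number of genes of each list with a peak midpoint in an exon (vertical axis), 1 bar per library, with the number of members in brackets under the horizontal axis. Trichome genes had 9 and 7 genes with peaks in wild-type replicates 1 and 2 and 0 in mta, and the cytosolic ribosome list had 16 in wild-type replicate 1 against 4 in replicate 2.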

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

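The results here concern peaks outside the protein-coding comparisons, singled out because both mta libraries had a larger share of them than both wild-type libraries; all these comparisons were chosen after the peaks had been seen, and no explanation was tested for them.

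Peaks with their midpoint in an exon of a noncoding gene made up 4.81% ± 0.295 of mta peaks and 0.866% ± 0.106 of wild-type peaks (SD, n = 2 each; exact permutation p = 0.333, the smallest possible). The numbers were 89 and 105 in mta and 71 and 62 in wild type. Small nucleolar RNA genes, which guide modification of ribosomal RNA, stood apart in number too: 24 and 24 had a peak in mta replicates 1 and 2, against 3 and 2 in wild type. In number, the other noncoding classes went both ways. Long noncoding RNA genes with a peak numbered 8 and 13 in mta against 22 and 21 in wild type. Genes annotated only as noncoding RNA numbered 13 and 11 against 18 and 17. The mta lists were shorter, so fewer genes there do not mean a lower share of peaks. Transfer RNA genes numbered 4 and 7 in mta against 0 and 1 in wild type, and transcribed pseudogenes 9 and 21 against 7 and 5. Genes annotated as miscellaneous RNA numbered 8 and 9 against 5 and 3. SNOR105 (AT1G29071; chromosome 1, 10151668 to 10151774) and SNOR108 (AT5G41471; chromosome 5, 16598796 to 16598905), chosen after their values were seen, had a peak in both mta lists and in neither wild-type list.

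Peaks on the chloroplast and mitochondrial genomes made up 1.19% ± 0.00409 of mta peaks and 0.0410% ± 0.0365 of wild-type peaks (SD, n = 2 each). They numbered 23 and 25 in mta and 6 and 1 in wild type. The chloroplast tRNA genes trnQ and trnD held peaks in both mta lists.

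Peaks on no annotated exon made up 4.43% ± 1.30 of mta and 1.19% ± 0.0771 of wild-type peaks (SD, n = 2 each), 68 and 112 in mta against 112 and 75 in wild type.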

How the results depend on the processing

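The alternatives for the 3' UTR share in peaks of at least 75 bp and in lists of equal length, and the replicate block for mta regions, were chosen after seeing the data. Of 71 values under an alternative, 44 stayed within the spread of their result or on its side of the test and 27 did not; the cause of the shifts below was not tested. The unknown read depth limits every count of missing peaks. The ratio of peak numbers and the 3' UTR shift kept their direction under each alternative run, though at scores of at least 50 the ratio of 0.289 came with overlapping libraries. That cutoff kept unlike shares of the lists, a limit on every value by score below. No gene list passed after adjustment in the alternatives where lists could be tested, and at scores of at least 50 none could; without wild-type replicate 1, defence had an unadjusted Fisher's exact p of 0.0413 (adjusted 0.207).

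The share of wild-type replicate 2 met by replicate 1 was 86.5% for overlap of at least 0.5 of the shorter peak, 82.8% for midpoints within 50 bp and 92.9% for scores of at least 50. In mta it was 16.3% at that score, where the list of replicate 2 is the longer one; of replicate 1, the shorter, 59.0% met replicate 2. Wild-type regions without an mta peak were 87.6% by midpoints within 50 bp, 82.4% with peaks within 100 bp shared, 87.3% by score, 82.4% in lists of equal length, 80.1% in genes with an mta peak elsewhere (a filter that itself favours absence at the region), and 86.1 to 90.02% without 1 replicate. The mta regions without a wild-type peak were 45.6% within 100 bp, 73.2% by score and 52.9 to 64.4% without 1 replicate. Genes without an mta peak numbered 471 (80.1%) by score, 839 (70.4%) in lists of equal length and 4143 to 5818 (74.3 to 82.1%) without 1 replicate, against 74.1% in the main analysis. The RRACH excess within 100 nt was 0.0173 points in wild type, not above all placements in both lists, and -0.915 in mta. In mta it lay above all placements in both lists within 25 nt (6.24 points), but not at 50 nt, where leaving out 1 mta replicate gave 2.88 to 3.11.

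The labels give both genotypes replicates 1 and 2 and do not say whether same-numbered libraries share a batch. Deviations of same-numbered libraries correlated at 0.0231 over 11522 regions. This cannot exclude a shared batch, since most regions found in both wild-type lists had no mta peak. With the replicate block, the mta to wild type ratio of peaks was 0.262 against 0.259, the 3' UTR share fell by 42.0 points in both, wild-type regions without a peak in the same-numbered mta list were 90.9% and mta regions without one in wild type 64.1%. The exact sign-flip test on 2 pairs cannot go below 0.5.

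Ranking by fold enrichment and the planned comparison of summit with midpoint were not run.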

Other observations

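The product families (the histone family was narrowed to core histones after a wider definition, which took in histone-modifying enzymes, had been tested), the UGUA and GGAU motifs, and the tests of the calling threshold, wide peaks and the ribosome list were chosen after the results had been seen; equal list length and RRACH in regions were planned, but their use as tests of an explanation was chosen after. The threshold test replaced a planned one on regions found in both wild-type lists, which those lists had themselves chosen, and then one on the highest rank group alone.

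Ribosomal protein genes, of the cytosol and the organelles together, had an mta peak anywhere in the gene more often than other genes; whether it was at the same site was not tested. By annotated product, 130 had a peak in both wild-type lists and 80 of these (61.5%) had none in mta, against 74.1% of all 5194 genes (Fisher's exact adjusted p = 0.0171 over 11 product families). Core histone genes were frequent among genes with peaks in mta alone: 6 of the 184 were histones, of 17 histone genes with a peak in any list (Fisher's exact adjusted p = 1.08e-05 over the same families). HTA6 and HTA11, H2A histones, and RAT5 were among them, named after their values were seen. COR15A, a cold-induced chloroplast protein, and SWEET11, a sugar transporter of phloem parenchyma, were the members of the fixed lists with a peak in both mta lists and in neither wild-type list.

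UGUA, contained in URUAY where R is G, was found within 50 nt of 66.7% ± 0.0109 of wild-type and 49.8% ± 2.17 of mta peaks (SD, n = 2 each), 13.5 and 8.34 percentage points above placement in the same gene and feature. Wild-type regions with an mta peak carried it more often than those without, at 75.3% against 70.3% (Fisher's exact adjusted p = 0.0241 over 5 motifs). Regions in mta alone, 74.4% of them in coding sequence, carried it in 39.0% of cases, against 66.7% of mta regions shared with wild type. Placement gave 34.3% and 52.4%, so much of that gap goes with gene and location, and the excess was 4.72 and 14.3 points. GGAU was at 40.8% and 31.7% in these sets (Fisher's exact adjusted p = 0.0122, which takes no account of location), where placement gave 32.4% and 26.8%, an excess of 8.47 and 4.84 points.

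The absence of mta peaks from most wild-type regions was set against a higher calling threshold in the mta libraries. Were that the only difference, mta peaks would meet a wild-type list about as often as the other wild-type list shortened to as many peaks. The mta peaks met at most 13.9% of a wild-type list's peaks, and the shortened lists met 33.0% and 44.2%. By this measure a threshold alone does not account for the absence. The lists were matched in number and not in width, which limits the test. Median widths were 56 and 54 bp in mta against 88 and 83 bp in the full wild-type lists, and wider peaks overlap others more easily. Lower read depth or antibody yield in the mta libraries is not excluded, because depth is unknown. Lists of equal length, which left 82.4% without an mta peak, cannot add peaks to mta. If all lists were called alike and low depth added no calls, lower depth alone would thin every class of peak. Coding-sequence peaks numbered 755 and 935 in mta against 697 and 548 in wild type. Small nucleolar RNA genes with a peak numbered 24 and 24 against 3 and 2. On that condition these values argue against lower depth as the only difference between the libraries. The condition was not tested: the calling settings are unknown, and the lowest score was 20 in mta replicate 2 against 13 elsewhere. Of the coding peaks of mta replicates 1 and 2, only 45.2% and 35.9% met the other mta list. Lower depth and antibody yield therefore both stay open. Lower m6A in mta leaves may also account for the absence and cannot be told apart from lower yield here: RRACH did not separate regions with and without an mta peak (Fisher's exact p = 0.161). URUAY, not named for that test, was more frequent in regions with an mta peak, at 64.8% against 59.9% (Fisher's exact adjusted p = 0.0249 over 5 motifs), the direction opposite to the one looked for in RRACH. That p-value takes no account of gene or location. Placement in the same gene and feature gave 53.4% and 50.2%, an excess of 11.4 and 9.68 points, so much of the gap goes with gene and location.

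The lower share of 3' UTR peaks in mta may have a technical origin, of which 2 were tested. Narrow calls near the minimum width do not account for all of it, since among peaks of at least 75 bp the mta minus wild type difference was still -26.5 points, although smaller than over all peaks. A fixed background of coding-sequence peaks called in both genotypes would place mta coding peaks on wild-type ones, but at most 13.5% of an mta list's coding peaks met a wild-type peak, against 80.1% and 75.9% of its 3' UTR peaks. Of the coding peaks of mta replicates 1 and 2, 45.2% and 35.9% met the other mta list. Because only called peaks were compared, a shared background that was left uncalled in wild type is not excluded. What the coding peaks are was not tested, and a difference between the genotypes stays open.

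No nuclear photosynthesis gene of the 55 had a wild-type peak, although random lists matched on 3' UTR length held 12.7 genes with a peak in both wild-type lists on average, and 0 of 10000 held none. Short 3' UTRs thus do not account for it. Reads shared between paralogs do not account for it either by this measure, as 54 of the genes had a 3' UTR with no match of at least 90% identity over 50 nt in another gene, and matched lists of that size held 12.4. High transcript abundance could hinder calls against background and is not excluded, since abundance was not measured here. Of the ribosome list, also abundant transcripts, 76.2% had a peak in either wild-type list. In both lists, the measure used for the matched lists, 19.0% (4 of 21) had one. For comparison, 5194 of 27562 protein-coding genes had a peak in both, a baseline that counts genes whether or not leaves express them. By annotated product, 130 of 344 ribosomal protein genes did. Yet the ribosome list had 16 genes with a peak in wild-type replicate 1 and only 4 in replicate 2. Of all 7434 genes with a peak in replicate 1, 5194 had one in both. These ribosomal genes thus do not settle whether abundance hinders calls. No biological explanation was tested.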
